A study of Arabidopsis thaliana with 18 samples.

How the data were processed

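PolyA RNA was sequenced from first leaves of Arabidopsis thaliana plants at 14 days of age. The plants were of 5 accessions (Ler-1, C24, Kro-0, Bur-0 and Col-0) and of the F1 crosses between Col-0 and each other accession, in 2 biological replicates per group, 18 libraries in all. The deposited files hold, for each library, a list of splicing events with 2 columns of counts and a PSI column. Per the labels, the genome build was TAIR10, and HISAT2 (no version given) and edgeR 3.0.8 were used; the role of each tool, the definition of an event, the counting rule and any filter were not given in the labels. The deposited counts are whole numbers of reads for each of the 2 forms of an event. The deposited PSI is a fraction, and in every event and library it equalled the reads of the second form divided by the reads of both forms plus 1. From how the counts followed the introns annotated in TAIR10.1, the first form is the spliced intron, the longer of 2 introns or the skipped exon, and the second form is the retained intron, the shorter of 2 introns (more sequence kept in the transcript) or the included exon. PSI is given below as a percentage.

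Events were of 4 types: intron retention (IR), alternative acceptor (Alt3), alternative donor (Alt5) and skipped exon (Skip_Exon). The Col-0 and Bur-0 lists were the same 6171 events, and those of C24, Kro-0 and Ler-1 held 5666, 5727 and 5916; each hybrid had the list of its parent other than Col-0. The lists differed almost only in IR events. The 5403 events common to all lists, in 2591 genes, were used for every comparison. Of the 1801 IR events among them, 1146 had a first intron annotated in TAIR10.1; the first intron of the other 655 was not annotated (called unannotated stretches), and these had a median PSI of 0.966 in Col-0 as a fraction. Gene symbols, strands, coding spans and sequences came from the TAIR10.1 RefSeq annotation and genome, whose chromosome coordinates were used as those of TAIR10. Intron lengths in each accession's own assembly were taken from the coordinates in its event names.

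Each accession was compared with Col-0, and each hybrid with the mean of its parents, by the edgeR (4.0.16, R 4.3.3) quasi-likelihood test on the 2 columns per library, with a term for each library and a form-by-group term, for events with at least 10 reads in each compared library. The 10 libraries of the pure accessions shared one fit for the parental comparisons, and all 18 libraries shared one for the hybrids. An event was called at a Benjamini-Hochberg adjusted p under 0.05. The effect of the fit is a log2 odds difference; since fitted odds are not bounded where a group had 0 reads of a form, PSI differences in percentage points are given instead, with the SD of the 2 libraries of a group. On the odds scale a parent with 0 reads of a form pulls the mid-parent to an extreme value, so hybrid values are given beside the PSI of the parents or of the mid-parent, with the calls that also passed limma (3.58.1) on PSI and the range of its adjusted p for the others. Event types and gene lists were compared with two-sided Fisher exact tests, and directions with exact binomial tests, each Benjamini-Hochberg adjusted within its family (SciPy 1.17.1, statsmodels 0.14.6, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9). Overlapping events of a gene share reads and are not independent.

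Libraries held 3186952 reads (C24 replicate 2) to 6134488 reads (Col-0 x Ler-1 replicate 2) over their listed events, with a median of 62 to 118 reads per event. Where a form had 0 reads, 3 reads of the total gave the upper limit; such limits cover counting error only, since the reads carry no molecular identifiers. The tests were tested on simulated data with the depth and spread of these libraries and 200 changed events: a log2 odds difference of 2 was recovered in 32% to 39% of parental and 39% to 56% of hybrid events, and one of 1 in 1% to 2% and 3% to 6%. The changed events were drawn only among events with a PSI away from both extremes, and simulated hybrids had parents of equal PSI. These recovery rates therefore do not cover events where a parent had 0 reads of a form. Between the replicates of a group the median absolute difference in PSI was 2.16 (Ler-1) to 2.87 (Col-0 x Bur-0) percentage points.

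The comparisons, tests, threshold, depth minimum, most alternatives, gene lists and the rule for named genes were chosen before the data were examined. The rule took, for each parental comparison, the 8 largest rises and 8 largest falls in PSI among called events whose 2 libraries of one group all lay above or below those of the other, 1 event per gene, and then at most 12 called events in genes of 9 fixed lists (clock, splicing factors, flowering, abiotic stress and ABA, immunity, photosynthesis, glucosinolates, light signalling, and markers of other cell types); for each hybrid, the 4 largest rises and 4 largest falls; and for sharing, 6 genes. The alternatives were depth minimums of 20 and 1 reads, DESeq2 (1.42.0), TMM and DESeq2 size factors, a replicate block, a PSI difference of at least 0.1, leaving out each library, and others added later, which are named where their effect is given. Replicate numbers are shared between groups but the labels do not say that they pair the libraries, so the main tests had no replicate block. Over 4154 events, the differences between replicates 1 and 2 correlated between groups at r of -0.16 to 0.30 (median 0.047). The correlation was above 0.1 in 13 of 36 pairs of groups, including Col-0 with each of its 4 hybrids (0.21 to 0.30), and 16 of 18 libraries matched best with their own number. Some pairing is therefore possible, and the block is given beside the hybrid counts.

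The hybrid files were not split by parental allele. The planned tests of allelic differences within hybrids, of parental against allelic differences, and of their relation across events were therefore not run, and cis and trans effects were not separated. Events listed for only some accessions were left out of the comparisons because at least 1 group had no values for them.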

Results

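Leaf splicing was measured by polyA RNA sequencing in 5 Arabidopsis thaliana accessions and in 4 F1 hybrids that share Col-0 as a parent, with 2 libraries in each of the 9 groups. Plants had grown for 14 days on plates with 1% sucrose, in days of 16 h light (100 µmol m-2 s-1, 22 °C) and 8 h dark (18 °C). Each value below is PSI in percent, the reads of the second form of an event divided by the reads of both forms plus 1. It is given as the mean ± SD of 2 libraries (n = 2). Percentages of reads below are PSI in this sense, which lies below the plain share where reads are few. TMT2 in Kro-0, for example, had 50 of 50 reads of the second form and a PSI of 95.8%. The second form is the retained intron, the included exon, or the splice site that keeps more sequence in the transcript. Total reads over the listed events were 5680940 and 5812703 in Col-0, 5124772 and 5141043 in Bur-0, 3636688 and 3186952 in C24, 4163691 and 4503606 in Kro-0, and 4817258 and 5752819 in Ler-1. The hybrids had 4004272 and 5250622 reads (Col-0 x Bur-0), 4346636 and 5492731 (Col-0 x C24), 4317428 and 4668935 (Col-0 x Kro-0), and 4458027 and 6134488 (Col-0 x Ler-1). Events in RBCS1A, the small subunit of Rubisco, took 13.7% to 24.4% of a library's reads over the events common to all lists.

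The comparison of Bur-0 with Col-0 asked where splicing had diverged between these parents. In AMY3 (AT1G69830), a plastid alpha-amylase, Bur-0 used an acceptor that kept 12 nt more of the coding span (chromosome 1, 26291698 to 26291709, TAIR10) in 99.0% ± 0.297 of reads. Col-0 had 0 of 1277 reads, which allows up to 0.235%. The reference sequence of the kept stretch with the 6 nt before it is TTTCTCTTGGATCTGTAG, and the adjusted p was 3.6e-13. GTB1 (AT1G65440), an SPT6-like transcription elongation factor, moved the other way: a donor keeping 24 nt (1, 24307709 to 24307732) fell from 98.4% ± 1.69 in Col-0 to 1.76% ± 2.49. ATG8E (AT2G45170), an autophagy protein, exchanged acceptors 3 nt apart on the 5' UTR side, with 99.5% ± 0.318 in Col-0 and 8.06% ± 11.4 in Bur-0. The magnesium transporter gene MGT2 (AT1G16010) gained a donor 52 nt away (0 of 205 reads in Col-0, 76.5% ± 1.64 in Bur-0). AHP5 (AT1G03430), a phosphotransfer protein of cytokinin signalling, rose from 6.35% ± 4.05 to 77.0% ± 4.30 at an acceptor 28 nt away.

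Among the other large rises in Bur-0 were the acceptors of AT3G52050 (0 of 31 reads to 97.7%), ATMAK3 (AT2G38130, 0 of 140 to 91.8%), CID7 (AT2G26280, 0 of 577 to 83.1%) and AT2G38330 (0 of 215 to 71.2%), and the donor of AT3G07510 (35.6% to 97.6%). The other large falls were in AT1G23130 (acceptor, to 6.62% from 7853 of 7853 reads), AT3G26920 (acceptor, 93.1% to 2.63%) and AT1G17145 (donor, 97.7% to 15.2%). Introns fell in AT1G01260, a basic helix-loop-helix transcription factor (94.2% to 10.8% retained), AT2G14255 (83.5% to 1.52%) and AT5G58980 (80.0% to 0 of 56 reads). All 16 of these events had an adjusted p of 1.27e-05 or below, and the hybrid mean lay between the parental means in all 16. Called events of list genes included FLK (AT3G04610), an RNA-binding promoter of flowering, whose 5' UTR intron fell from 26.4% ± 2.53 to 0.490% ± 0.693 retained. Retention rose in the splicing factor U2AF65A (AT4G36690, 29.7% ± 6.07 to 52.1% ± 3.43, adjusted p = 0.017) and in WRKY70 (AT3G56400), a defence transcription factor (9.0% ± 4.19 to 23.7% ± 4.17, adjusted p = 0.019). It fell in MVP1 (AT1G54030, 20.1% ± 2.21 to 8.13% ± 3.34). A 5' UTR donor of the clock gene GI (AT1G22770) fell from 2.57% ± 0.744 to 0 of 431 reads (adjusted p = 0.032). An unannotated 36 nt stretch of LHCB5 (AT4G10340), an antenna protein of photosystem II, had a PSI of 99.3% ± 0.310 in Col-0 (325 of 325 reads kept it) and 77.3% ± 2.68 in Bur-0. The reference has neither GT or GC at the start nor AG at the end of this LHCB5 stretch, nor of the stretches called in RBCS1A and LHCB6, so these values are not shown to be splicing. PHOT2 (AT5G58140), a blue-light receptor, and RBCS1A (AT1G67090) fell by 0.837 and 0.110 points, and the carbonic anhydrase gene CA1 (AT3G01500) rose by 0.714 points.

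In all, 460 of 5137 tested events (313 genes) were called between Bur-0 and Col-0, 234 higher and 226 lower in Bur-0, and 264 of them differed by at least 10 percentage points. The count was 238 without Col-0 replicate 1, 205 without Bur-0 replicate 1 and 209 without Bur-0 replicate 2, and limma on PSI called 300.

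C24 against Col-0 put the same question to the parents of a second cross. GGH3 (AT1G78670), a gamma-glutamyl hydrolase, used a donor 52 nt away (1, 29591914 to 29591965) at a PSI of 84.9% ± 11.3 in C24 and in 0 of 653 reads in Col-0. Only 23 and 2 reads of the 2 forms stood behind the C24 value, and the hybrid was at 3.51% ± 1.41. TMT2 (AT4G35300), a vacuolar sugar transporter, rose from 24.3% ± 7.64 to 90.9% ± 7.27 at a 5' UTR donor. The Alfin-like gene AL6 (AT2G02470) rose from 43.3% ± 8.94 to 98.7% ± 0.311 at an acceptor. A 69 nt stretch of SR34b (AT4G02430), an SR splicing factor (4, 1071216 to 1071284), had a PSI of 95.9% ± 0.929 in Col-0, where 48 of 48 reads kept it. Its PSI was 5.12% ± 4.30 in C24. The corresponding intron measured 82 nt in the C24 assembly. LARP6a (AT5G46250), an RNA-binding protein, fell from 99.6% ± 0.0909 to 25.3% ± 2.46 at donors 6 nt apart.

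The remaining large rises in C24 were in AT3G13410 (acceptors 3 nt apart, 0 of 746 reads to 50.3%), RBL6 (AT1G12750, donor, 2.70% to 50.2%), AT1G10657 (acceptor, 9.24% to 54.1%), AT3G07510 (donor, 35.6% to 97.6%) and AT3G63445 (25% to 69.5%, an intron without GT or GC and AG at its ends on the assigned strand). The remaining large falls were in AT2G04790 (donor, 97.3% to 0 of 56 reads), AT3G57810 (donor, 97.4% to 4.17%) and AT3G10760 (acceptor, 97.9% to 13.3%). Introns fell in AT2G14255 (to 6.25%), AT5G58980 (to 2.94%) and AT2G39280 (73.4% to 0 of 41 reads). Among list genes, SR30 (AT1G09140), another SR factor, gained 6.11% ± 0.946 of an acceptor without a read among 626 in Col-0. FLK fell to 3.03% ± 2.66 retained and MVP1 to 6.40% ± 0.217. The LHCB5 stretch fell to 68.4% ± 0.182, and CA1 rose by 0.740 points.

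Of 5033 events, 303 (218 genes) were called, 131 higher and 172 lower in C24, and 194 differed by at least 10 points. Without any 1 of the 4 libraries compared, 131 (C24 replicate 1) to 170 (Col-0 replicate 2) events were called. TMM scaling of each form on its own, tried after the data were seen, called 369 and lowered the share of higher events from 43.2% to 30.1%.

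In Kro-0, ORP2A (AT4G22540), an oxysterol-binding protein relative, lost an acceptor on the 3' UTR side (4, 11860713 to 11860780). Its PSI was 99.4% ± 0.168 in Col-0, with 0 of 351 reads of the other form, and 0 of 174 Kro-0 reads used it. The hybrid stood at 46.5% ± 1.53. AT4G25030 fell from 99.1% ± 0.0775 to 0.527% ± 0.0585 at an acceptor 19 nt away, with an adjusted p of 5.5e-13, and the 69 nt stretch of SR34b fell to 0.909% ± 1.29. Retention of an intron of EMB2654 (AT2G41720), a pentatricopeptide repeat protein, rose from 47.5% ± 10.3 to 98.0% ± 0.561. MGT2, TMT2, AL6 and AT3G13410 also rose in Kro-0, to 68.9% ± 9.30, 95.8% ± 1.85, 99.1% ± 0.0873 and 55.4% ± 2.12.

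Further large rises in Kro-0 were in AT3G52050 (acceptor, 0 of 31 reads to 96.7%), AT1G48610 (donor, 0 of 61 reads to 66.7%) and IQD30 (AT1G18840, donor, 46.1% to 94.8%). Further large falls were in AT1G53780 (acceptor, 96.0% to 0 of 63 reads) and AT3G08650 (acceptor, 91.4% to 0 of 27 reads). Introns fell in AT2G14255 (to 0 of 93 reads), AT1G01260 (to 11.6%) and AT5G58980 (to 0 of 29 reads). In the lists, FLK fell to 0 of 202 reads and MVP1 to 4.15% ± 2.15. The splicing factor RS40 (AT4G25500) fell from 24.3% ± 1.32 to 12% ± 0.0275 at a donor 583 nt away (adjusted p = 0.046). CA1 and LHCB6 (AT1G15820) rose by 0.745 and 0.112 points.

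Of 5063 events, 263 (197 genes) were called, 97 higher and 166 lower in Kro-0, and 168 differed by at least 10 points. DESeq2 called 175, and the count was 152 without Col-0 replicate 1 and 153 without Kro-0 replicate 2.

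In Ler-1, GIP1 (AT4G09550), a small protein of gamma-tubulin complexes, rose from 8.97% ± 0.619 to 98.7% ± 0.0453 at an acceptor 8 nt away on the 5' UTR side (4, 6039687 to 6039694). ZML1 (AT3G21175), a GATA transcription factor, fell from 98.6% ± 0.129 to 0 of 57 reads at acceptors 15 nt apart (3, 7424536 to 7424550). PAT1 (AT5G48150), a GRAS protein of phytochrome A signalling, rose from 49.2% ± 1.12 to 98.4% ± 0.194 at a 5' UTR acceptor. The auxin response factor ARF1 (AT1G59750) rose from 63.0% ± 3.82 to 97.2% at donors 6 nt apart. AT5G42530 rose from 0.323% ± 0.105 to 54.1% ± 3.97, but its first form had 25797 reads in Col-0 and 42 in Ler-1.

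Further large rises in Ler-1 were in AT3G07510 (donor, to 98.1%), IQD30 (donor, to 92.1%), RBL6 (a 5' UTR acceptor, 56.4% to 95.6%) and AT3G42150 (donor, 9.66% ± 13.7 to 43.8% ± 3.40, adjusted p = 0.021). Further large falls were in AT4G38520 (acceptor, 98.4% to 0.714%), AT2G32910 (acceptor, 97.6% to 18.3%), and LARP6a (to 28.3%). Introns fell in AT2G14255 (to 1.61%), AT5G58980 (to 3.52%) and AT2G39280 (to 0 of 61 reads). An unannotated 295 nt stretch of AT1G70620, without AG at its end in the reference, fell from 99.2% to 26.4%. Its removal uses the same junction as the AT1G70620 acceptor described below as shared between accessions, so these are not separate changes. WRKY70 retention rose to 26.3% ± 13.1 and FLK retention fell to 0.885% ± 1.25. In the same lists, an acceptor of the splicing factor SR34 (AT1G02840) fell from 11.6% ± 1.90 to 4.63% ± 1.05 (adjusted p = 0.034). An unannotated stretch of FAMA (AT3G24140), a guard cell transcription factor, without AG at its end in the reference, fell from 99.4% ± 0.0486 to 94.2% ± 2.69, LHCB5 fell to 75.3% ± 7.29, and CA1 and RBCS1A rose by 0.748 and 0.0187 points.

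Of 5136 events, 358 (251 genes) were called, 144 higher and 214 lower in Ler-1, and 201 differed by at least 10 points. Without any 1 of the 4 libraries compared, 168 (Col-0 replicate 1) to 219 (Col-0 replicate 2) events were called. DESeq2 called 230 and limma on PSI 220.

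**Figure D1:**
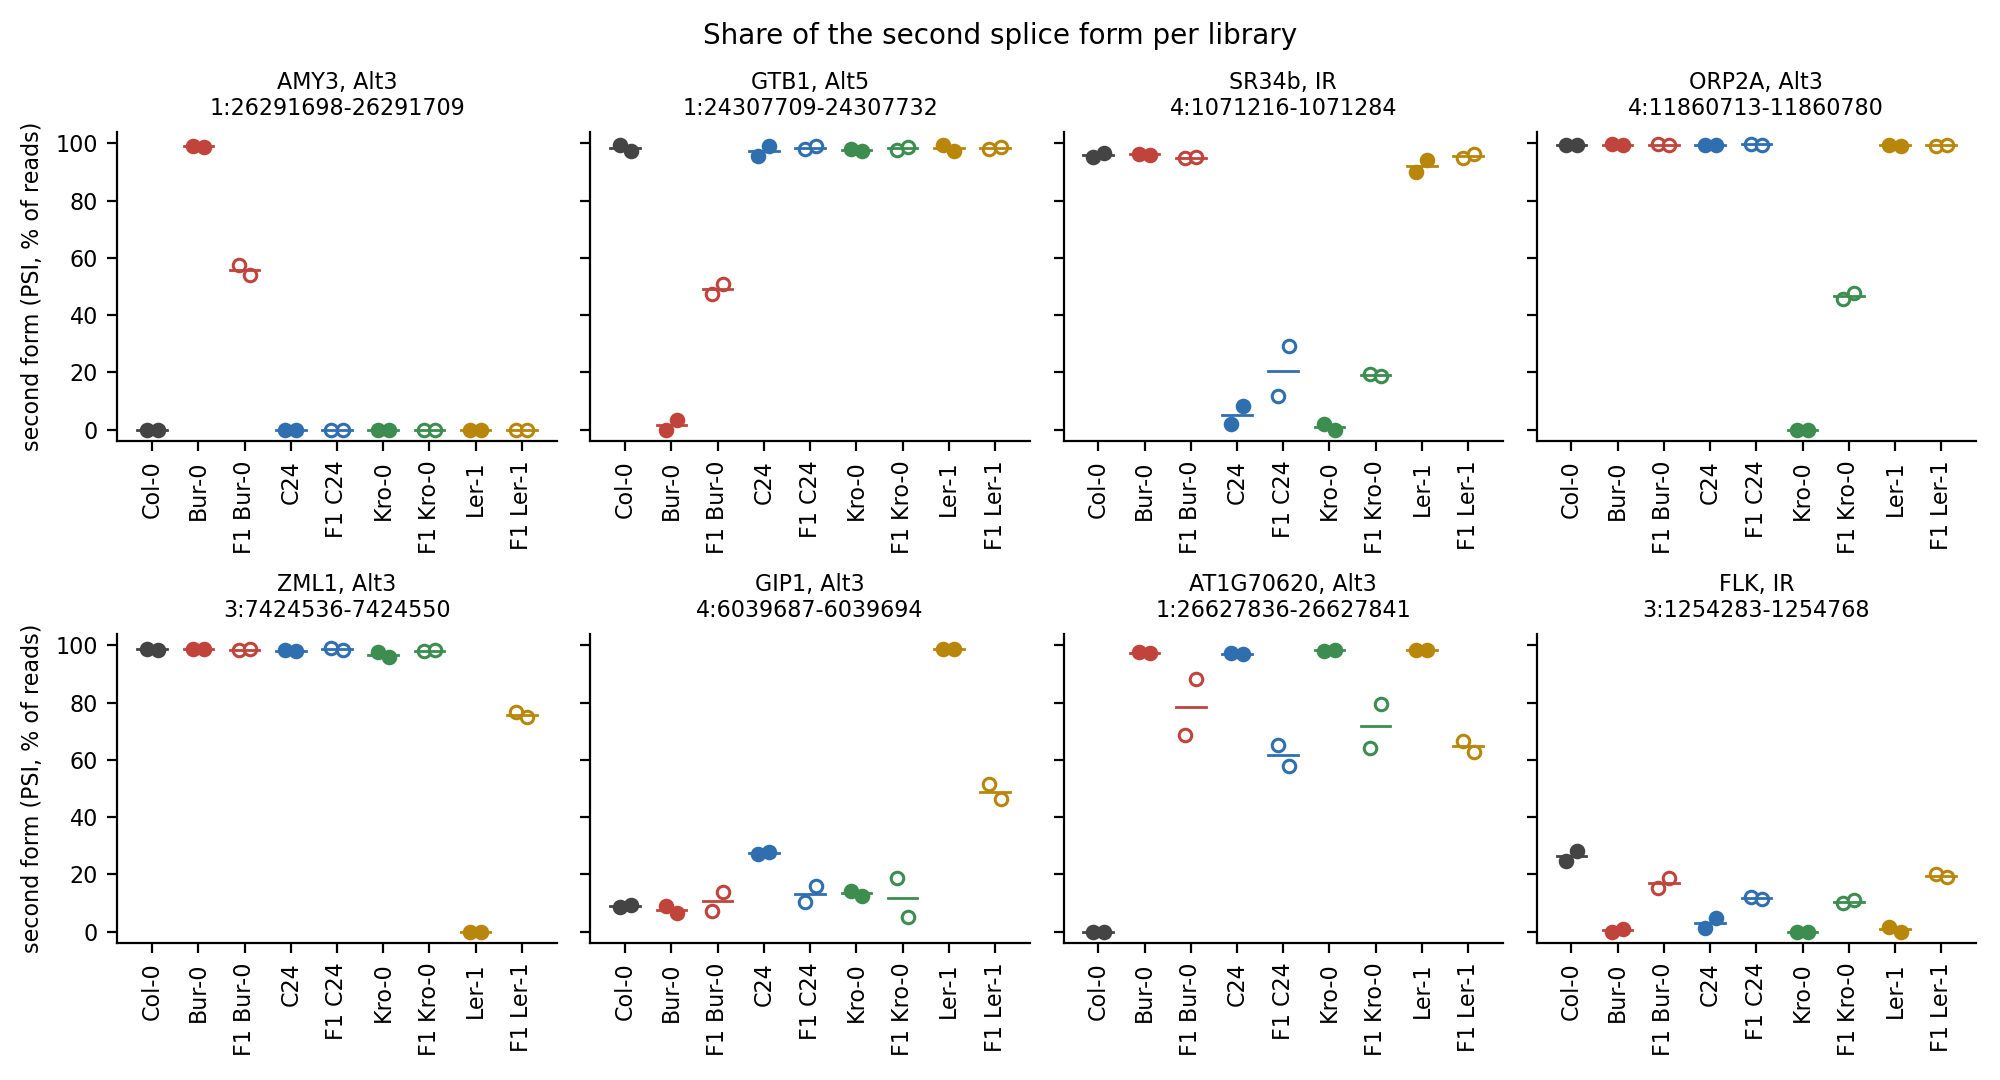
PSI (percent, reads of the second form over the reads of both forms plus 1) of 8 named events in each of the 18 libraries. Filled points are accessions, open points F1 hybrids and bars the mean of 2 libraries. AMY3, GTB1, ORP2A and ZML1 changed in 1 accession, and AT1G70620 and FLK differed from Col-0 in all 4.

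The fixed gene lists held called events in every comparison, but no list passed a test for more or fewer genes with a called event than other tested genes (two-sided Fisher exact tests, 9 lists in 4 comparisons, all 36 adjusted p = 1.0). The lists held few tested genes, so these tests could miss differences. The 1 tested glucosinolate gene was called in Bur-0, and its unadjusted p was still 0.12 (Fisher exact test). Over the 4 comparisons a called event was found in 5 of 24 tested splicing factors (RS40, SR30, SR34, SR34b and U2AF65A), 4 of 14 photosynthesis genes (CA1, and LHCB5, LHCB6 and RBCS1A without splice site letters), and 1 of 9 clock genes (GI). It was found in 1 of 6 flowering genes (FLK), 1 of 6 light signalling genes (PHOT2), 1 of 2 immunity genes (WRKY70), 1 of 2 markers of other leaf cell types (FAMA), the 1 glucosinolate gene (MVP1) and 0 of 5 genes of abiotic stress and ABA. Adjusted over the list alone, genes with a called event numbered 0 splicing factors, 3 flowering and 2 immunity genes in Bur-0. In the other comparisons the counts adjusted over the list alone were 2 (C24), 1 (Kro-0) and 0 (Ler-1) for splicing factors, 1 for flowering in each, and 1, 1 and 2 for immunity. For photosynthesis they were 3 in Bur-0, 3 in C24, 2 in Kro-0 and 3 in Ler-1. The stress list had 1 in C24, the glucosinolate list 1 in each comparison, light signalling 1 in Bur-0, other cell types 1 in Ler-1, and clock none.

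Intron retention events made up more of the calls than of the tested events in C24 and Kro-0. In C24, 137 of 1744 retention events were called (7.86%, against 5.05% of the other types, odds ratio 1.60, adjusted p = 0.00085), and in Kro-0 129 of 1753 (7.36% against 4.05%, odds ratio 1.88, adjusted p = 1.6e-05). Alternative acceptors were called less often than other types in C24 (4.55% against 6.82%, adjusted p = 0.0066) and Kro-0 (4.07% against 5.81%, adjusted p = 0.032). Those other types include the retention events. Donors and skipped exons were called in 5.79% and 5.05% of cases in C24, and in 4.08% and 3.79% in Kro-0. The acceptor result is therefore not separate from the retention result. The other 12 of the 16 two-sided Fisher exact tests did not pass. Among calls with a PSI difference of at least 10 points 12 of the 16 passed, and retention events were called more often than other types in all 4 accessions (odds ratio 2.1 in Bur-0 to 3.20 in Kro-0, highest adjusted p 8.1e-07). A 10-point cut depends on the PSI an event starts from, which was not matched between types. Called retention events were more often lower than higher in the accession: 103 against 26 in Kro-0 (adjusted p = 7.8e-11, exact binomial test), 97 against 47 in Ler-1 (adjusted p = 3.0e-04), and 85 against 52 in C24 (adjusted p = 0.032). The C24 lean did not pass with limma on the logit (76 against 60, exact binomial p = 0.20, not adjusted). Nor did it with all events listed for that pair in a fit of only the 4 libraries (79 against 58, exact binomial p = 0.087, not adjusted). Kro-0 and Ler-1 passed in both settings. The split of 99 against 76 in Bur-0 did not pass (adjusted p = 0.22), but after centring on the median log odds it was 106 against 68 (exact binomial p = 0.0049, not adjusted). Against the mean of the other 3 accessions Bur-0 had 70 lower and 93 higher (exact binomial p = 0.085, not adjusted). In Bur-0 the split moved with the library left out: it was even without Col-0 replicate 1. It leaned to lower without Col-0 replicate 2 or either Bur-0 replicate. Bur-0 also leaned to lower with DESeq2 (72 against 44, exact binomial p = 0.012, not adjusted) and limma on PSI (80 against 43, exact binomial p = 0.0011, not adjusted). With limma on the logit it did not pass (73 against 68, exact binomial p = 0.74, not adjusted). In a fit of only the 4 libraries compared, with all events listed for that pair, 97 were lower and 189 higher. Among the events common to all lists that fit had 87 lower and 64 higher.

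**Figure D2:**
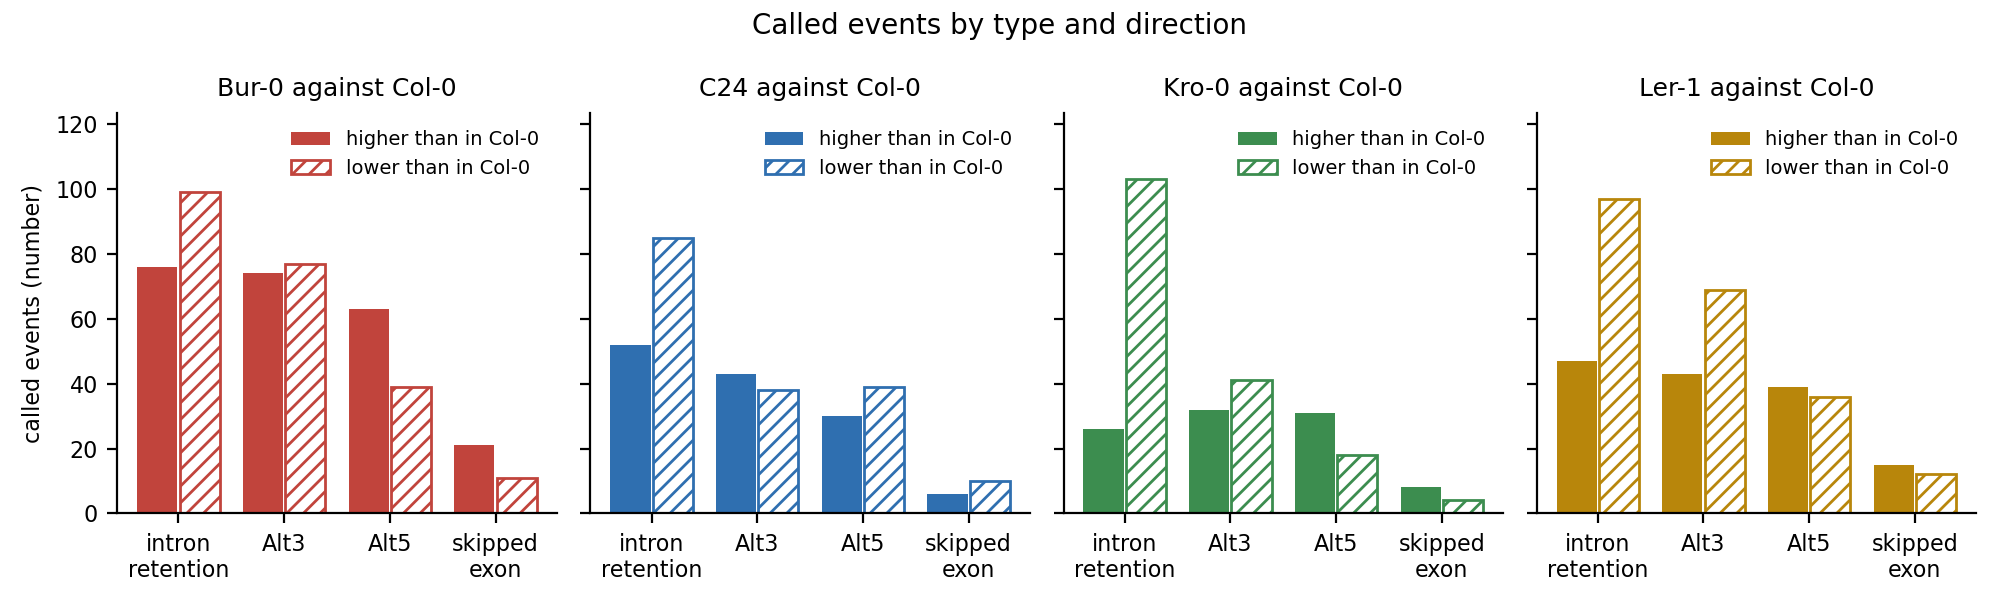
Number of called events per comparison by event type, higher (filled bars) or lower (hatched bars) in the accession than in Col-0. Lower intron retention events outnumbered higher ones most in Kro-0, at 103 against 26.

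Whether accessions shared their differences from Col-0 was asked over the 4937 events tested in all 4 comparisons. The 6 genes with the largest mean difference among events called with 1 direction in all 4 were led by AT1G70620, whose acceptor 6 nt away (1, 26627836 to 26627841) had 0 of 46 reads in Col-0 and 97.1% to 98.4% in the 4 accessions. Its hybrids stood between 61.6% and 78.6%. The introns of AT2G14255, AT5G58980 and AT2G39280 were retained in 83.5%, 80.0% and 73.4% of Col-0 reads and in at most 6.25%, 3.52% and 2.27% in any other accession. AT1G19485 fell from 73.0% ± 4.21 to between 5.21% and 12.2%, and AT4G16710 from 77.8% ± 2.33 to between 22.7% and 37.5%. FLK, CA1 and EXPA1, a cell wall expansin, were also called in all 4; EXPA1 was picked after its values were seen.

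Of 882 events called in at least 1 accession, 614 (69.6%) were called in 1 alone. With the same direction, 263 were called in 2 or more, 136 in 3 or more, and 58 (43 genes) in all 4, 33 of them higher and 25 lower than in Col-0. Independent lists of these sizes would share 0.0033 higher and 0.010 lower events among all 4. That expectation leaves out that the 4 comparisons used the same Col-0 libraries, which alone makes their differences correlate. Over all events the correlation of PSI differences between 2 accessions was 0.370 (Bur-0 and Ler-1) to 0.448 (C24 and Ler-1). It was 0.401 to 0.464 in simulated unchanged groups that shared simulated Col-0 libraries. The same sign was found in 64.2% to 66.6% of events, against 64.5% to 65.1% in the simulation. The covariance was larger, at 0.0032 to 0.0038 against 0.00083 to 0.00086. The simulation drew all groups, Col-0 included, with a spread pooled over the accessions. Between the real Col-0 replicates the chi-square per event for the share of the second form was 3.20. It was 1.67 (C24) to 2.24 (Kro-0) in the other accessions. That measure also grows with read depth, and median reads per event were 110 and 114 in Col-0 and at most 98 in the other accessions. The median absolute PSI difference between replicates was 2.30 points in Col-0, against 2.16 (Ler-1) to 2.40 (C24). Whether the simulation understates the covariance that comes from Col-0 is therefore open. The 10 simulated draws gave 0 events called in 2 or more accessions. At that pooled spread, this bears on false calls through shared controls and not on how far lists of true differences would overlap. Without Col-0 replicate 1 the events called with the same direction in 2 or more fell to 130.

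The hybrids asked whether the splicing level of an F1 lay midway between its parents. At the events called between the parents, the median hybrid stood 0.52 (Bur-0), 0.49 (C24), 0.48 (Kro-0) and 0.47 (Ler-1) of the way from Col-0 to the other parent, and 96.7%, 93.4%, 93.5% and 92.7% of hybrid means lay between the parental means. In Col-0 x Ler-1, 55.7% of hybrid means lay closer to Col-0 (exact binomial p = 0.034, not adjusted). With differences of at least 10 points this was 60.0% (median position 0.449, exact binomial p = 0.0057), and with at least 30 points 56.9% (exact binomial p = 0.32). In Col-0 x Bur-0 it was 63.2% with at least 30 points (median position 0.448, exact binomial p = 0.013). No other such test passed, with all called events or with either cut. AMY3 and ORP2A were near the middle, at 55.9% ± 2.45 in Col-0 x Bur-0 and 46.5% ± 1.53 in Col-0 x Kro-0. ZML1 stayed nearer Col-0 in Col-0 x Ler-1 (75.8% ± 1.13), and AT1G23130 did so in Col-0 x Bur-0 (94.7% ± 2.36). SR34b stood nearer C24 (20.5% ± 12.3) and Kro-0 (19.1% ± 0.614) in their hybrids. In all of these the nearer parent had more reads: the 2 forms of AT1G23130 had 7853 and 0 reads in Col-0 and 39 and 562 in Bur-0, and the second and first forms of SR34b had 48 and 0 in Col-0, 5 and 90 in C24 and 1 and 109 in Kro-0. The mid-parent weighs both parents equally, so unequal reads of the parents alone would shift a hybrid this way. These positions reuse the parental libraries that chose the events. In a check added after the data were seen, which left Col-0 libraries out, each accession was set against the mean of the other 3 accessions and its hybrid against the mean of the other 3 hybrids. The 2 differences had the same sign in 80.0%, 74.8%, 69.6% and 71.4% of these events in the Bur-0, C24, Kro-0 and Ler-1 crosses.

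**Figure D3:**
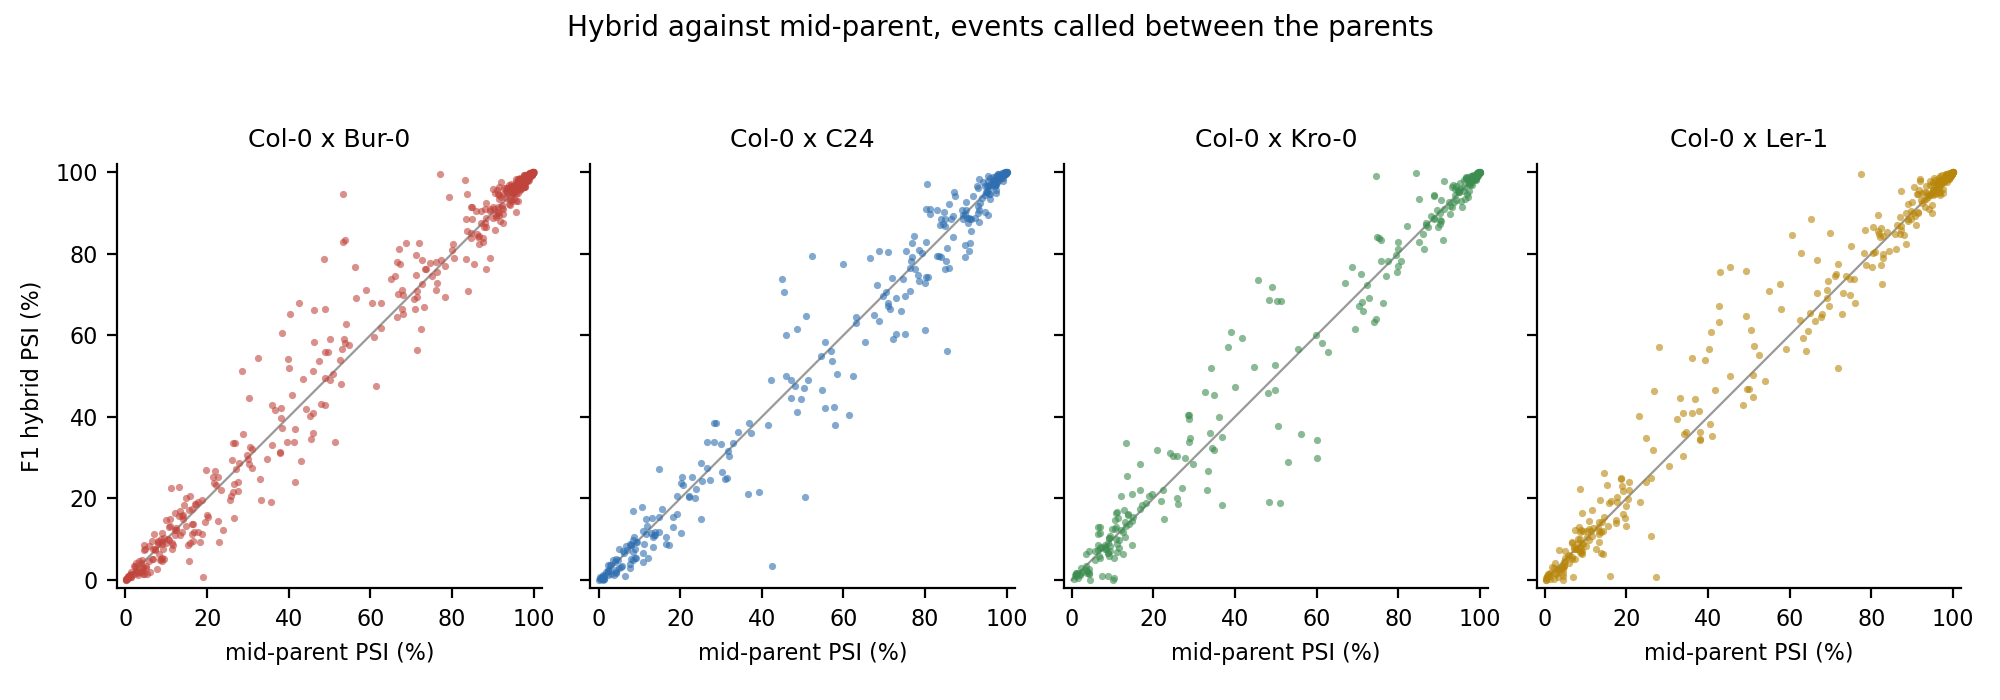
PSI of each F1 hybrid (percent, mean of 2 libraries) against the mean PSI of its parents for the events called between those parents; the line marks equality. Median positions between the parents were 0.47 to 0.52.

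Tested against the mid-parent, 5 of 5101 events were called in Col-0 x Bur-0, 3 of 5023 in Col-0 x C24, 4 of 5030 in Col-0 x Kro-0 and 7 of 5118 in Col-0 x Ler-1, in 15 genes. In Col-0 x C24, AK-HSDH I (AT1G31230), an enzyme of threonine and methionine synthesis, was above both parents at a 5' UTR acceptor: 20.2% ± 1.1, against 0.238% ± 0.337 in Col-0 and 3.57% ± 3.47 in C24 (adjusted p = 0.0047, and 7.9e-05 with limma on PSI). In Col-0 x Bur-0, ATPI4K ALPHA (AT1G49340), a phosphatidylinositol 4-kinase, was below both at a donor (81.2% ± 0.374 against 98.2% and 97.7%, adjusted p = 0.039, limma on PSI 0.105). In Col-0 x Ler-1, Cpn60beta2 (AT3G13470), a plastid chaperonin, retained an intron in 22.2% ± 2.75 of reads against 17.3% ± 2.50 in Col-0 and 0 of 586 in Ler-1 (limma on PSI 0.414). AT5G42530 was close to Col-0 in that hybrid at 2 overlapping acceptors, 0.862% ± 0.342 and 99.6% ± 0.0293. LARP6a was below the mid-parent in the C24, Kro-0 and Ler-1 hybrids (50%, 56.0% and 56.2%, against mid-parents of 62.5%, 62.7% and 63.9%).

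The other calls were AtkdsA1 (AT1G79500, intron retained in 54.3% of hybrid reads, mid-parent 39.9%), AT4G00585 (donor, 18.4%, mid-parent 14.5%) and AT5G14920 in Col-0 x Bur-0. AT5G14920 was called as lower (log2 odds difference -3.89), though its PSI of 78.4% lay above the PSI mid-parent of 72.8%. AT3G13410 had 28.6% and 29.9% in the C24 and Kro-0 hybrids, with mid-parents of 25.1% and 27.7%. AT1G54410 was above both parents by 0.416 points from the mid-parent in Col-0 x Kro-0. In Col-0 x Ler-1 the rest were G-TMT (AT1G64970), of tocopherol synthesis (51.9%, mid-parent 71.8%), Tic32-IVa (AT4G23430), of the chloroplast import machinery (84.7%, mid-parent 87.0%), and AT5G61820 (1.59%, mid-parent 1.04%). EXPA1 in Col-0 x Bur-0 and ALDH11A3 in Col-0 x Kro-0, named here after their values were seen, lay within 0.210 points of the mid-parent PSI. In 15 of the 19 calls a parent had 0 reads of a form, and 3 of the 19 passed limma on PSI (AK-HSDH I at 7.9e-05, AT4G00585 at 0.000119 and the 48 nt acceptor of AT5G42530 at 0.0219). The limma adjusted p of the other 16 was 0.0608 (G-TMT) to 1.0. At an unadjusted p under 0.05 there were 330, 369, 365 and 403 events in the Bur-0, C24, Kro-0 and Ler-1 hybrids. DESeq2 called 9, 6, 8 and 7, limma on PSI 20, 11, 14 and 3, and edgeR with a replicate block 7, 6, 10 and 8. In Col-0 x Bur-0, leaving out any 1 library left 0 or 1 call, and in Col-0 x Ler-1 2 to 4; Col-0 x Kro-0 fell to 2 calls without Kro-0 replicate 2 or its own replicate 2.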

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

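For the lean of retention events, the test with thinned reads was chosen only after the result of an earlier depth test was seen, and the others were set out before; for introns of another length, the test of read numbers was chosen only after the result was seen; and for the events shared by all 4 accessions, both tests were chosen only after the result was seen.

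Called retention events were mostly lower than in Col-0 in Kro-0 (103 of 129), Ler-1 (97 of 144) and C24 (85 of 137). A library-wide shift of retained reads could give this, but after centring on the median log odds 69.6%, 63.3% and 62.0% were still lower (exact binomial p = 3.9e-05, 0.0021 and 0.0061), which speaks against it as the whole cause. Such a shift was present in Kro-0, where 69.5% of 1036 uncalled annotated introns were also lower (median -2.67 points). Centring changed the Kro-0 split from 103 against 26 to 78 against 34, so part of that lean went with the shift. Lower depth in the accession is another candidate explanation; with reads thinned to equal numbers 77.9%, 66.7% and 63.8% were lower (exact binomial p = 2.1e-09, 0.00023 and 0.0060), again against it as the whole cause. The earlier test kept only events with at least as many reads in the accession as in Col-0, and there the lean passed in Kro-0 alone (13 lower and 4 higher, exact binomial p = 0.049; Ler-1 28 and 15, p = 0.066; C24 6 and 5, p = 1.0). Event lists may have been chosen for introns retained in Col-0. Against the mean of the other 3 accessions C24 had 50% lower (60 of 120), as this explanation predicts. Kro-0 had 78.3% (exact binomial p = 3.8e-09) and Ler-1 59.7% (exact binomial p = 0.043). This comparison was not centred, so a library-wide shift could also give the leans in Kro-0 and Ler-1. It therefore cannot decide on the event lists there. Of the 1146 annotated introns, 0.087% had a PSI under 0.05 as a fraction in Col-0, against 3.1% (Bur-0) to 4.3% (Kro-0) in the other accessions. In the hybrids it was at most 0.26%. Lists chosen for retention in Col-0 would leave such a floor, so this explanation stays open in all these accessions. How much of the lean it gives was not tested. No biological explanation was tested, and accession genotype stays open as untested.

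Called events had a first intron of another length in the accession assembly more often than uncalled events: 43.5% against 14.1% in Bur-0, 42.6% against 15.1% in C24, 36.1% against 12.2% in Kro-0 and 43.0% against 13.4% in Ler-1. Reads of 1 form could be lost where sequences differ, but the rising form gained reads, with a median ratio of 0.957 between its change in reads and its change in share (exact binomial p = 7.9e-17 over 327 pairs of event and accession, which share Col-0 libraries and repeat some events; p = 3.5e-13 over 152 with 1 per gene), against this as the whole cause. Longer introns could hold more length differences and be called more often. Yet the odds ratio pooled over 4 classes of intron length was lowest in C24, at 4.51 (95% interval 3.51 to 5.79). Overlapping events of a gene might be counted more than once, but with 1 event per gene the lowest odds ratio was 3.62 (Fisher exact p = 6.7e-16); both values speak against these as the whole cause. Differences in how events were defined in each assembly, and sequence differences that change splicing, were not tested.

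The 58 events called in 1 direction in all 4 accessions could reflect a deviation of the Col-0 libraries alone. The hybrids, which are other libraries, had a median position of 0.519 between Col-0 (0) and the accessions (1), and all 58 lay on the Col-0 side of the accession mean (exact binomial p = 6.9e-18). For 18 retention events lower in the accessions the listing may have fixed this side, since no listed annotated intron lacked a retained read in a hybrid. The 13 higher retention events, 14 acceptors, 10 donors and 3 skipped exons lay on that side as well. This argues against a deviation of the Col-0 libraries alone as the whole cause. A deviation shared by the Col-0 and hybrid libraries is not excluded. Differences between replicates in Col-0 correlated with those in each hybrid (0.21 to 0.30) and in Kro-0 (0.21). With Bur-0, C24 and Ler-1 the correlation was -0.014, -0.043 and -0.16. The exact binomial p counts events that share these libraries, and some share a gene. Reads of 1 form might be lost in all 4 accessions where they differ from Col-0; the median ratio of the change in reads to the change in share was 0.753, with 20 of 35 events above 0.5 (exact binomial p = 0.50), so this and a true change of splicing cannot be told apart. This pattern was found and tested in the same data and remains a hypothesis.

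In 10 cases events moved in opposite directions from Col-0 in 2 accessions, each with an adjusted p under 0.05 between those accessions. AT2G02570 retention was 94.5% in C24 and 30.9% in Kro-0 (63.6 points apart, Col-0 58.3%). In AT4G16670, 2 introns differed by 61.2 points (82.4% in Bur-0, 21.1% in Ler-1) and 55.0 points (81.4% and 26.4%), and AT3G61210 retention by 40.1 points (65.2% in Bur-0, 25.1% in Kro-0). TMT2 differed by 69.3 points at a donor (94.2% in C24, 24.9% in Ler-1), AT2G43160 by 49.8 points at an acceptor (75.9% in Bur-0, 26.1% in Ler-1) and TIFY8 retention by 31.1 points (31.1% in C24, 0 in Kro-0). AT3G05160 was higher in Kro-0 than in Ler-1 by 22.9 points at an acceptor, 15.9 at a donor and 10.4 at a skipped exon, events that share reads. The hybrids did not follow at TMT2 (76.1% and 75.5%) or at the first of the AT4G16670 introns (56.2% and 60.8%), so these 2 rest on the accession libraries alone.

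Some events were listed for an accession and its hybrid but not for Col-0, so they had no comparison here. With over 3 reads of both forms in both libraries of the accession there were 98 in C24, 96 in Kro-0 and 206 in Ler-1. Median PSI over all such events regardless of reads (120, 134 and 250) was 28.3%, 15.9% and 27.9%.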

How the results depend on the processing

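Counts of called events moved with the method. In Bur-0, 460 became 300 with limma on PSI, 311 with DESeq2 and 264 with a PSI difference of at least 0.1. C24 went from 303 to 227 with DESeq2 and 194 with at least 0.1, Kro-0 from 263 to 175 and 168, and Ler-1 from 358 to 230 and 201, or 220 with limma on PSI. Leaving out 1 library gave 205 to 322 in Bur-0, 131 to 170 in C24, 152 to 195 in Kro-0 and 168 to 219 in Ler-1. The cause of these moves was not tested.

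The hybrid counts were small and moved more. Col-0 x Bur-0 had 5 calls, 9 with DESeq2, 20 with limma on PSI, 35 with limma on the logit, 2 with at least 0.1 and 0 to 1 with a library left out. Col-0 x C24 had 3, then 6 with DESeq2, 6 with a replicate block, 11 with limma on PSI, 20 on the logit, and 3 whichever library was left out. Col-0 x Kro-0 had 4, then 8, 10, 14 and 25 in that order, 0 with at least 0.1 and 2 to 5 with a library left out. Col-0 x Ler-1 had 7, then 3 with limma on PSI, 4 with at least 0.1 and 2 to 4 with a library left out. AT5G14920 in Col-0 x Bur-0 was reversed: log odds fell by 3.89 against the mid-parent while its PSI was 0.056 above it as a fraction, since the log-odds mid-parent is extreme where Col-0 had 0 reads of a form.

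With TMM scaling of each form on its own, the share of higher events in C24 fell from 43.2% to 30.1%. Events called with the same direction in 2 or more accessions went from 263 to 153 with at least 0.1, and to 130 to 185 without 1 Col-0 library. Of the 16 tests of event types 4 passed, and 12 with at least 0.1.

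The alternatives for allelic differences, for parental minus allelic differences and for at least 50 reads in their comparison were not run, as the hybrid reads were not split by allele.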

Other observations

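Of 1738 alternative acceptors, 29 had no AG at the second acceptor in the reference, a class picked after the data were seen. In 21 of these Col-0 had no reads of that form, and 18 of the 21 were called in at least 1 accession. The labels do not say how events were listed, so whether the listing fixed this number and its direction is open. AMY3 (TC), AT1G70620 (AC), CID7 (TT), AT2G38330 (AT), AT3G13410 (GG) and SR30 (AT) were among the 29.

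Within the coding span, alternative sites and exons that kept the reading frame were called more often than those that shifted it (161 of 811, 19.9%, against 229 of 1638, 14.0%, odds ratio 1.52, adjusted p = 0.0019, Fisher exact test). Tests of place and frame were not among the planned ones. Starting PSI and read depth were not matched between the classes, so a difference in the power to call events could also give this. The other 6 of 7 tests of place and frame did not pass. Among these, acceptors 3 nt apart were called in 9 of 64 cases (14.1%, against 16.3% of other acceptors, odds ratio 0.840, adjusted p = 0.73).

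Of 728 events tested between Bur-0 and Col-0 that were not listed for all accessions, 135 were called, 125 higher and 10 lower in Bur-0. Of the corresponding 135, 171 and 246 events of C24, Kro-0 and Ler-1, 5, 4 and 11 were called higher and 0, 0 and 4 lower. Since the listing rule is not known, it is open whether it fixed these directions. Of the 1146 annotated introns, none lacked a retained read in Col-0 or in any of the 4 hybrids (lowest PSI 2.53% in Col-0 and 2.92% to 5.13% in the hybrids), and 7, 6, 13 and 12 did in Bur-0, C24, Kro-0 and Ler-1.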
